A study of Mus musculus with 2 samples.

How the data were processed

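The series holds 2 RNA sequencing libraries of mouse forebrain at embryonic day 11.5, from the strain B6NCrl. Per the labels, replicate 1 was made from the forebrains of 109 embryos and replicate 2 from those of 88 embryos, of both sexes. Total RNA above 200 nucleotides was extracted, and each library started from 1 cell-equivalent of it, following a SmartSeq protocol, which copies and amplifies the complementary DNA before sequencing. The assay is titled single cell RNA-seq in the labels, but the source is pooled tissue, so each library was treated as 1 bulk sample. Spike-in RNAs were added, per the labels.

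The authors deposited a gene table and a transcript table for each library. Per the file headers, these tables hold expected counts, which are estimated numbers of reads per gene or transcript and need not be whole. The authors' tables also give TPM (transcripts per 1000000 transcripts) and FPKM (fragments per kilobase of effective length and per 1000000 reads), both as a point estimate and as a posterior mean. The percent of a gene's TPM that falls to each transcript is given in the deposited transcript tables. The posterior SDs and interval limits in the deposited tables were read as a score with no fixed range. The text deposited with the tables names the mouse assembly mm10 and gene annotation release M4. The aligner and the quantification program are not given in the sources used here, and neither is the use of strand, so reads of a gene and of an overlapping or antisense gene may not be separable. Effective lengths were shorter than lengths by 99 bases. TPM as deposited covers all rows, spike-ins included, so a larger spike-in share lowers the TPM of every gene.

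Each gene table has 43346 gene rows, 96 rows of ERCC spike-ins, 1 phiX row and 26248 rows whose ID is a bare number. These numbered rows have a median length of 73 bases, and 99.8% of them have an effective length of 0, so they can hold no reads. They and the spike-ins were left out of gene counts and tests. Symbols, gene classes and coordinates were taken by gene ID from GENCODE release M21, which uses the same assembly, mm10. It matched 42462 of the 43346 gene IDs (98.0%), and the unmatched IDs held 0.151% and 0.167% of the gene counts. Coordinates are 1-based and those of release M21.

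There is one group of 2 samples, so no groups were compared and no p-value is given. Genes were called detected at a TPM of at least 1. Agreement was measured as Pearson r and Spearman rho of log2(TPM + 1) across genes with a mean TPM of at least 1, with an error from 200 bootstrap draws of genes. Genes are not independent replicates. A difference between the libraries is replicate 2 minus replicate 1 on the log2(TPM + 1) scale, which understates the change of low genes. Genes with a mean TPM of at least 10 and an absolute difference of at least 1 were counted as differing 2-fold. The spread beyond counting is the common biological coefficient of variation from edgeR 4.0.16 with an intercept alone and TMM scaling, on expected counts rounded to whole numbers, for genes with at least 10 counts over both libraries. Its error comes from 20 bootstrap draws. The effective number of molecules came from the squared coefficient of variation, less its Poisson part, averaged in 20 bins of mean TPM and fitted as a constant plus a term that falls with TPM.

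The 24 gene lists and the rule for the genes to be named were fixed before the data were examined, as were most of the tests and alternatives. Those added or rewritten afterwards are named where their results are given. From each list, the rule takes the 3 members of highest mean TPM among those detected in both libraries, or the highest member where none was. It adds Emx2, Pax6, Sox2, Dlx2, Eomes, Tbr1, Tubb3, Nkx2-1, En1 and Hba-x at whatever level, the 10 most abundant genes, and the 10 protein-coding genes in each direction with the largest difference at a mean TPM of at least 10. Some genes that the rule takes are not reported here. Other genes named here were chosen after their values were seen. For lists with at least 3 members at a mean TPM of 1, the median difference was placed among 10000 random lists of the same size, each member drawn from the 100 genes nearest in mean TPM.

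A count of 0 was taken to allow up to 3 counts, or 0.105 and 0.104 CPM (counts per 1000000 counts) at the depth of each library. Shares of counts carry 95% Clopper-Pearson intervals. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

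The molecule estimates, the coefficient of variation, the count of 2-fold genes and the list test were tried on simulated data, and the other steps were not. With 50000 molecules drawn for the real levels over 8270 genes, the binned estimate gave 49054, and with 5000000 molecules it gave 4844700. Genes read in one library alone are, here and below, those with under 1% of their depth-scaled counts in the other. An estimate from them gave 47265 at 50000 molecules but ran to its limit of 2565240 at 200000 when no amplification noise was simulated, and at 5000000. The estimate from squared differences gave 47510 at 50000, 180032 at 200000 and 3761860 at 5000000. The real fit took 11107 genes, and there the estimates from bins, squared differences and one library alone lay far apart, at 277548, 37266 and 56851. The simulation at 50000 molecules did not reproduce that gap, so its close recovery does not vouch for the real estimate from bins. A known coefficient of variation of 0.2 was recovered closely, and larger ones were underestimated by less than 5%. Under counting noise alone, 0.0526% of unchanged genes and 98.5% of genes changed 3-fold were called 2-fold different. Of 200 random lists of 15 genes, 3.00% lay outside the central 95% unshifted, 28.0% after a shift of 1 on the log2 scale and 96.0% after a shift of 3. The list test therefore had little power for a 2-fold shift.

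The alternatives covered detection thresholds, pseudocounts, level filters, FPKM and posterior means, centring, TMM and DESeq2 1.42.0 size factors, and each library alone. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.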

Results

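RNA from mouse forebrain at embryonic day 11.5, when the telencephalic wall is made mostly of dividing progenitors and the first neurons are being born, was measured in 2 replicate libraries. Replicate 1 came from a pool of 109 embryos and replicate 2 from a separate pool of 88 embryos, and each library was built from an amount of RNA equal to that of 1 cell. The libraries held 28639678 and 28948074 expected counts. The design has one group, so the questions it can address are which genes the tissue expressed and how closely the replicate libraries agreed. Values are TPM in replicate 1 and replicate 2, in that order, unless a mean ± SD with n = 2 is given.

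At a TPM of at least 1, 7207 genes were detected in both libraries, 6531 of them protein-coding. Replicate 1 had 8928 detected genes and replicate 2 had 9813, and 1721 and 2606 of these passed in one library alone.

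At a TPM of at least 1 in both libraries, most genes listed as telencephalon-wide regulators were present and none of those listed for midbrain, hindbrain and Hox clusters. Of 8 genes listed as telencephalon-wide regulators, which need not be confined to the telencephalon, 7 were detected in both libraries. The orphan nuclear receptor gene Nr2f1 was the highest, at 132 ± 24.6 TPM (SD, n = 2), followed by Nr2e1 at 55.8 ± 16.3 and the head homeobox gene Otx2, at 86.3 and 23.6 TPM. En1, a midbrain and hindbrain gene (chromosome 1, 120602418 to 120607992 on mm10), had 0 counts in both libraries. None of the 12 midbrain and hindbrain genes was detected in both. All 39 Hox genes matched, Hoxb6 among them, had 0 counts in both libraries. By counting error alone this allows up to 0.105 CPM (counts per 1000000 counts) for each. That limit applies to the libraries and not to the tissue. Of genes with a mean TPM from 10 to 20, 43.3% had under 1% of their counts in one library, so expressed genes can be missed.

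Genes of the dorsal telencephalon, which gives rise to cortex, were detected in both libraries for 8 of 11 members. Pax6 (ENSMUSG00000027168.17, chromosome 2, 105668900 to 105697364) was at 85.6 and 30.1 TPM, Lhx2 at 47.0 and 42.1, and the proneural gene Neurog2 at 27.3 and 23.6. Pax6 had 2720 and 1714 counts, a smaller gap than in TPM. Emx2 (chromosome 19, 59458372 to 59465357) was at 20.6 and 7.95 TPM. Of 15 ventral telencephalic genes, 6 were detected in both libraries and 7 in one alone. Isl1 was at 76.1 and 67.5 TPM, Gad2, which encodes a GABA-synthesising enzyme, at 25.4 and 80.2, and Dlx1 at 46.3 and 38.1. The gap of Gad2 was much smaller in counts, at 3207 and 4131. Dlx2 (chromosome 2, 71543408 to 71546754) was nearly confined to replicate 2, at 0.13 and 22.7 TPM from 7 and 1196 counts, while Nkx2-1 was at 10.1 ± 4.11 (SD, n = 2). Hem and dorsal midline genes were detected in both for 3 of 9 members and in one alone for 3 more. Msx1 stood at 50.5 and 55.1 TPM, Msx2 at 33.2 and 34.7, and Wnt8b at 2.85 and 38.7. Diencephalic and hypothalamic genes were detected in both for 3 of 15 and in one alone for 3 more. Those in both were Tcf7l2 at 153 and 56.7 TPM, Lhx5 at 13.4 and 21.5, and Lhx9 at 3.60 and 8.47. Lhx9 had 370 and 361 counts, so it differed in TPM but hardly in counts.

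Most progenitor genes and all cell cycle genes listed were detected in both libraries. Of 21 neural progenitor genes, 18 were detected in both libraries. The intermediate filament gene Vim was at 741 and 1290 TPM, the radial glial gene Fabp7 at 438 and 1010, and Ccnd2 at 246 and 284. Sox2 (chromosome 3, 34650405 to 34652461) was at 21.8 and 18.9 TPM, which is 20.4 ± 1.98 (SD, n = 2). All 24 cell cycle genes were detected in both, and their summed TPM was 4908 and 4943. The ribonucleotide reductase gene Rrm2 was at 462 and 691 TPM, Cdk1 at 444 and 432, and Ccnb1 at 466 and 399.

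Genes of neurogenic progenitors were detected in both libraries for 9 of 14 members, with Hes6 at 66.2 and 169 TPM, the antiproliferative gene Btg2 at 95.7 and 105, and Gadd45g at 87.8 and 33.9. Eomes, which marks intermediate progenitors of the cortex, was at 5.47 and 8.19 TPM. Of 29 genes of young neurons, 15 were detected in both and 9 in one alone. The neuronal tubulin gene Tubb3 (chromosome 8, 123411424 to 123422015) was at 512 and 356 TPM, Stmn3 at 322 and 250.5, and Stmn2 at 176 and 187. Tbr1, expressed by early cortical neurons, was at 17.9 ± 16.8 (SD, n = 2). Of 12 genes listed for mature glia, only Pdgfra was detected in both libraries, at 9.74 and 10.1 TPM, and 1 other in replicate 1 alone. The remaining 10 were detected in neither, so Pdgfra alone does not show mature glia.

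**Figure D1:**
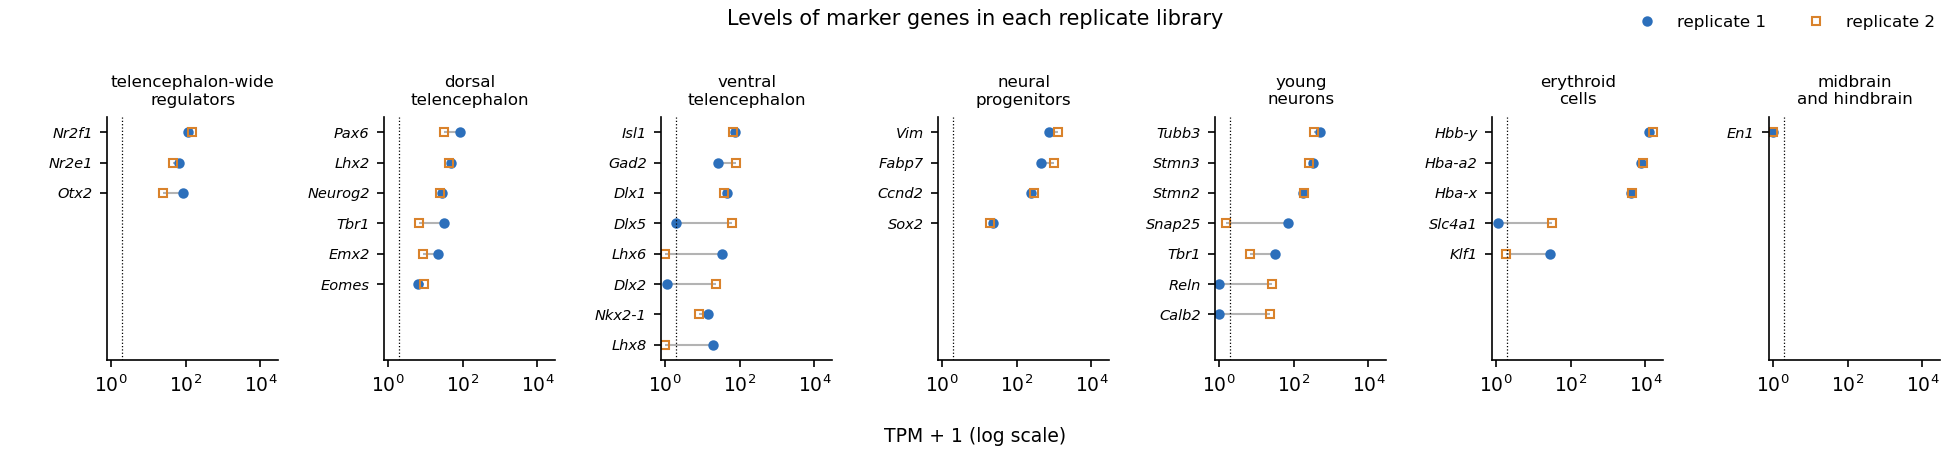
TPM + 1 on a log axis for genes named in the text from 7 gene lists (some chosen after their values were seen), with filled circles for replicate 1, open squares for replicate 2 and a grey line between them; the dotted line marks a TPM of 1. Hbb-y reaches 12348 and 16181 TPM, the progenitor gene Vim 741 and 1290, and the midbrain and hindbrain gene En1 lies at 0 in both libraries.

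Blood made a clear contribution. The 8 haemoglobin genes held 1.35% of the counts in replicate 1 (95% interval 1.34 to 1.35) and 1.60% in replicate 2 (1.59 to 1.60). The embryonic globin gene Hbb-y (ENSMUSG00000052187.3, chromosome 7, 103851749 to 103853216) was the most abundant gene in the tissue, at 14264 ± 2710 TPM (SD, n = 2). Hba-a2 was at 7689 and 8703 TPM, and Hba-x, an embryonic alpha-type globin gene, at 4019 and 4454. Hba-a2 is nearly identical to Hba-a1, so how reads were divided between that pair is uncertain. Of 14 erythroid genes, 8 were detected in both libraries.

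The genes of other lists, most of them for non-neural cell types, left smaller traces. Endothelial genes were detected in both libraries for 5 of 13 members and in one alone for 3 more, with Esam at 44.8 and 47.3 TPM, Egfl7 at 31.6 and 31.4, and the VEGF receptor gene Kdr at 14.3 and 17.2. Genes of mesenchyme, meninges and pericytes were detected in both for 5 of 16 and in one alone for 6 more, with Lum at 169 and 62.6 TPM, Col3a1 at 85.8 and 117, and Col1a1 at 66.1 and 70.3. Of 13 surface ectoderm genes, Krt8 at 73.9 and 2.59 TPM and Cdh1 at 13.1 ± 2.97 (SD, n = 2) were detected in both and 4 others in one alone. Of 13 myeloid genes, Fcer1g at 65.8 and 23.3 TPM and Csf1r at 15.7 and 2.86 were, with 3 others in one alone. None of 10 eye genes was detected in both, and the 2 that were detected, of which Dct was the highest at 0 and 21.6 TPM, had 0 counts in replicate 1. Of 8 genes listed for neural crest and peripheral nervous system only Th was detected in both, at 30.9 and 16.5 TPM. The other 7 were detected in neither, so Th alone does not show such cells. None of 10 immediate early and heat shock genes was detected in both, and the highest, Jun, had 0 and 25.7 TPM.

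All 15 imprinted genes were detected in both libraries, led by Mest at 748 and 1431 TPM, Snrpn at 257 and 163, and the non-coding RNA Meg3 at 203 and 171. Of 10 long non-coding RNA rows, 7 were detected in both, with Malat1 at 5064 and 6717 TPM and H19 at 92.1 and 123. Hypoxia and glycolysis genes were detected in both for 7 of 11, with Ldha at 2106 and 1818 TPM, Pgk1 at 490 and 573, and Bnip3 at 130 and 195. Of 5 sex-linked genes 4 were detected in both. The X-inactivation RNA Xist was at 23.1 and 50.9 TPM, and the Y-linked genes Eif2s3y and Kdm5d were at 27.5 and 16.2 and at 10.3 and 21.6.

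After Hbb-y and Hba-a2, the most abundant genes were Gm28437 at 7586 ± 210 TPM (SD, n = 2), mt-Atp6 at 7212 ± 463, the ferritin gene Ftl1 at 6477 ± 522 and the histone gene Hist1h2ap at 6449 ± 116. They were followed by mt-Atp8 at 6405 ± 441, Gm22133 at 5896 ± 320, Malat1 at 5891 ± 1169 and the cyclophilin gene Ppia at 5678 ± 623. Gm28437 is annotated as an unprocessed pseudogene on chromosome 1, and its deposited interval of 1511 to 7590 TPM in replicate 1 leaves its level uncertain. That of mt-Atp6, 4721 to 8199 TPM in replicate 1, is also wide. Gm22133 is annotated as a microRNA gene inside the bounds of Ftl1, so its reads cannot be told from those of Ftl1. Gm22133 had 1370 and 1258 counts, against 132982 and 117070 for Ftl1. Its place among the most abundant genes in TPM thus reflects a very short gene and not many reads. Mitochondrially encoded genes held 1.64% and 1.77% of the counts, ribosomal protein genes 3.49% and 3.36%, and histone genes 0.251% and 0.258%. The ERCC spike-ins held 4.35% and 3.35%. As shares of TPM, which weight short transcripts more, the means of the libraries were higher, at 3.56% for haemoglobin genes, 3.03% for mitochondrially encoded genes, 7.52% for ribosomal protein genes, and 0.842% for histone genes, and the spike-ins held 8.44% in replicate 1 and 6.56% in replicate 2.

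How closely the libraries agreed depended on the level of the gene. Abundant genes such as Ldha, Hbb-y and Malat1 lay close together, and of 139 genes with a mean TPM of at least 1000 none differed 2-fold, with a median absolute log2 difference of 0.18. Genes at the level of some patterning regulators did not. Of the 2129 genes with a mean TPM from 10 to 20, the range that holds Emx2, Tbr1, Dlx2 and Nkx2-1, 43.3% had under 1% of their counts in one of the libraries. That share was 16.4% from 20 to 50 TPM, 3.57% from 50 to 100 and 0.240% from 100 to 200. Across 11107 genes with a mean TPM of at least 1, Pearson r was 0.492 (bootstrap SD 0.00815) and Spearman rho 0.526. Pearson r was lower, at 0.387, over the 7680 genes with a mean TPM of at least 10, and 0.769 over the 1658 genes with at least 100. The r was sensitive to the pseudocount and the filter, from 0.290 to 0.818.

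**Figure D2:**
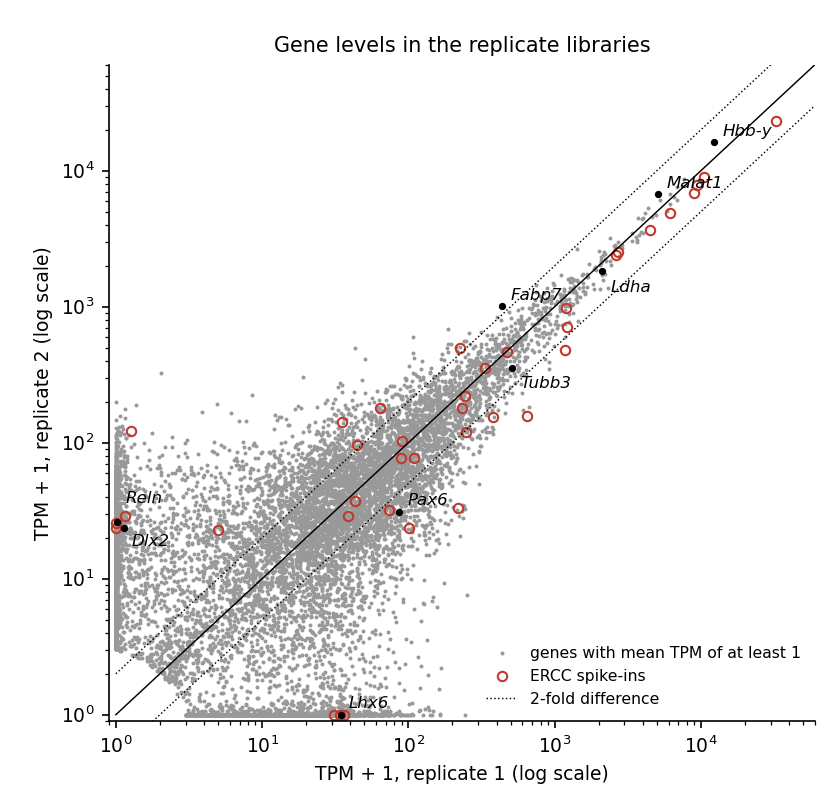
TPM + 1 of each gene with a mean TPM of at least 1 in replicate 1 (horizontal) and replicate 2 (vertical), both axes logarithmic, with ERCC spike-ins as open circles, the line of equality and dotted lines at 2-fold. Genes read in one library alone lie along the axes, Reln and Lhx6 among them (labelled after their values were seen), and Pearson r over the 11107 genes is 0.492.

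Of 7680 genes with a mean TPM of at least 10, 3940 (51.3%) differed 2-fold, 2042 of them higher in replicate 2 and 1898 higher in replicate 1. With 1 library per pool, these differences have no replicate check. Those genes had a median of 2336 summed counts, so most were read deeply in the library that held them, and 1391 of them had under 1% of their counts in the other. The largest differences were all of that kind. Pnkd was at 241 TPM in replicate 1 with 0 counts in replicate 2, at least 1130-fold higher in CPM against a floor of 3 counts. Hist1h2ag and Chrac1 were also at 0 counts in replicate 2, and Tex9, Guk1, Zpr1, Tmem109, Fam118b, Rcl1 and Ftsj1 had 1 to 5 counts there against 117 to 164 TPM in replicate 1. In the other direction, Mgst1, which encodes a microsomal glutathione transferase, was at 198 TPM in replicate 2 with 0 counts in replicate 1, at least 964-fold higher. Fuca1 and 1500011B03Rik were likewise at 0 counts in replicate 1. Dctn6, Atp6ap2, Pdlim1, Yipf3, Pts and the mitotic kinase gene Ttk had 2 to 5 counts there, and Myg1 had 18 against 5096. Guk1, for instance, had 2752 counts against 1, a ratio of 2811 with a 95% counting interval of 504 to 111049.

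**Figure D3:**
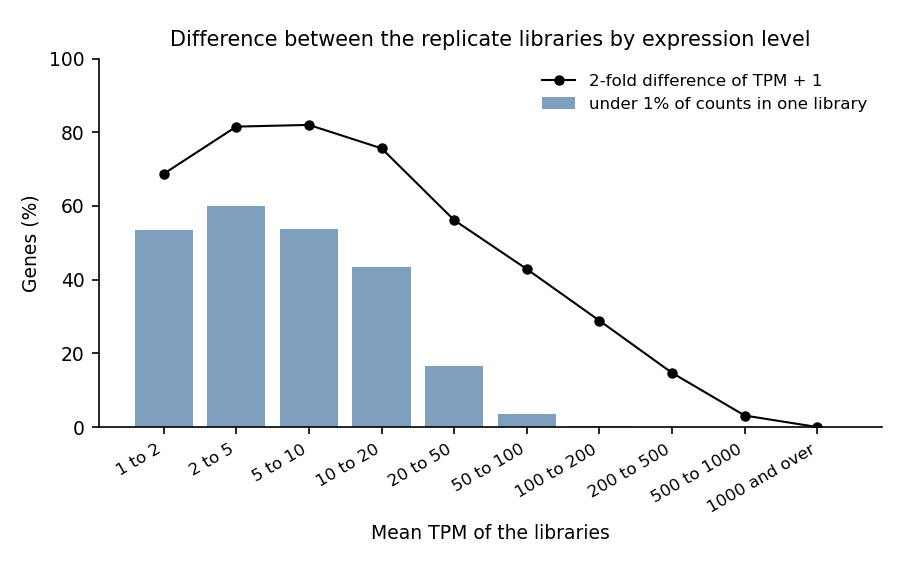
Percent of genes, by mean TPM of the libraries, that had under 1% of their counts in one library (bars) or differed 2-fold in TPM + 1 (line and points). The bars stand at 43.3% for genes from 10 to 20 TPM and at 0.240% from 100 to 200.

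The spread beyond counting, as a common biological coefficient of variation, was 1.69 (bootstrap SD 0.00942) over 12218 genes. It depended on level, with a median of 2.53 at an average log2 CPM of 1 to 3, 1.17 at 5 to 7 and 0.426 above 9. The square root of the median gene-wise dispersion by DESeq2 was 0.750. The squared coefficient of variation was fitted to the gene level as if from sampling molecules, which gave 277548 per library (bootstrap SD 10453). The fitted form keeps rising at low levels, but the bin values did not, at 1.31 near 1.39 TPM and 1.35 near 10.7 TPM. With 2 libraries this measure has an upper limit, reached when all counts lie in one library, so it could not follow the fitted form at low levels. The fit therefore did not describe the spread at all levels. This fit had been planned as the main one and gave the highest of 6 distinct estimates, the lowest being 36341, so the number is uncertain by more than its bootstrap SD. A chi-square statistic of the counts over these genes was 659 per degree of freedom, so the tables are not copies of one library.

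Among gene groups, the 24 cell cycle genes had a median difference of -0.01, with 12 higher in each library, and the 20 neural progenitor genes with a mean TPM of at least 1 had a median of 0.20. The median over all genes with a mean TPM of at least 1 was 0.12, but this came mostly from low genes. It was 1.02 from 2 to 5 TPM and 0.02 over genes with at least 10. Lists of abundant genes are therefore better read against random lists of matched level than against 0.12. Of 19 lists with enough members, 1 lay outside the central 95% of random lists of matched level, against 0.95 lists from chance. This was the erythroid list, at a median of 0.32 and percentile 98.1, with 9 of 10 members higher in replicate 2. Its median was 0.20 after the 0.12 of all genes was removed, which takes off too much for abundant genes. With the mean in place of the median, 0 lists lay outside. The erythroid difference was 0.36 as a mean, so its place outside the random range depended on that choice while its size did not. Dorsal telencephalic genes had a median of -1.27, with 7 of 9 higher in replicate 1, at percentile 5.79. Surface ectoderm genes had a median of -2.41 at percentile 5.45, but over 4 members, 3 of them higher in replicate 1. More genes of that list were detected in replicate 2 (5) than in replicate 1 (3). Myeloid genes had a median of -2.12 at percentile 9.42 over 5 members, 4 of them higher in replicate 1. Genes of young neurons had a median of -0.44 at percentile 9.27 that turned to 0.19 as a mean. In the other direction, long non-coding RNAs had a median of 0.97 at percentile 93.5, with 7 of 9 higher in replicate 2. Only 4 of the lists had a range of random lists narrow enough to show levels 2-fold higher in replicate 2.

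Of 47 genes chosen for isoforms, 34 had a gene TPM of at least 5 in both libraries, and 23 of these (67.6%) had the same leading transcript in both. The leading transcript of Pkm held 88.9% and 92.5% of its TPM, that of Actb 99.2% and 99.5%, and that of Hmga2 99.9% and 99.6%. For Pax6 the leading transcript of replicate 1, at 32.8%, had 0% in replicate 2. Genes with the same leading transcript had a median mean TPM of 132, and the others 58.6.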

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

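The test of a different mix of cells was chosen after the result it bears on had been seen, as were the estimates of molecules from squared differences and from genes read in one library alone. The test of shared reads was planned on medians, which were 0 for both sets of genes, and means were put in their place afterwards.

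Rows whose ID is a bare number held 23.0 expected counts in replicate 1 and 26.0 in replicate 2. They stood out because they lie outside the genes and spike-ins and exceed the 3 counts that a count of 0 allows. Nothing in the tables says what they are.

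The first pattern is the wide spread between replicate libraries of the same tissue, seen in regulators such as Dlx2 and Wnt8b and little in genes such as Ldha. The effective number of molecules was 277548 by bins, 37266 from squared differences of genes with a mean TPM of at least 50 and below 1000, and 56851 from genes read in one library alone. All lie under the 1000000 that was set beforehand as the most that 1 cell-equivalent could hold, which is consistent with the labelled input limiting the libraries. The number counts sampled molecules only if the spread came from sampling and not from a difference between the pools of embryos. A larger input copied at low efficiency would give the same value and stays open. No biological explanation was tested for this pattern, since the design has one group.

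The second pattern is the set of 3940 genes that differed 2-fold, from Pnkd to Mgst1. Counting noise argues poorly for it, since 0.711% of these genes lay within the 99% binomial range. At their median of 2336 summed counts a 2-fold difference nearly always lies outside that range, so this follows from depth and selection and adds no separate support. After a smooth trend on GC content and length was removed, 96.0% kept their difference, and their ratio of estimator SD to mean count was 0.650 times that of genes of the same level that did not differ, which speaks against shared reads as the whole cause. The spike-ins, which come from no embryo, spread 1.49 times as much as genes of matched level, with 19 of 38 over 2-fold, and 1.05 times as much after their common shift of -0.27 was removed. A candidate explanation is therefore the sampling and amplification of few molecules, but with 1 library per pool this comparison cannot exclude a different mix of cells, the gene lists (1 of 19 outside its random range) had little power when tried first, and a difference between the pools of embryos stays open.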

How the results depend on the processing

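No paired analysis was possible because there is one group. No p-value was computed, so the only calls that could be gained or lost were those of the gene lists. The estimates from squared differences and from genes read in one library alone, the rescaling without spike-ins, the stricter chi-square filter and detection in at least 1 library were added after seeing the data. Pearson r was 0.290 with a pseudocount of 0.1, 0.726 with 10, 0.818 with no filter on level, 0.387 at a mean TPM of at least 10, 0.503 with FPKM and 0.598 with posterior means. The count of 2-fold genes was 6663 at a mean TPM of at least 1 (3694 higher in replicate 2 and 2969 in replicate 1), 899 at 50 (428 and 471) and 2384 at 4-fold (1307 and 1077), as the stricter settings test fewer genes or ask more. It stayed within 1.5 times under the other 7 settings, including both scalings of counts. By CPM, 3607 of the 3940 genes differed 2-fold the same way and 10 the opposite way. The coefficient of variation was 1.68 with at least 100 counts and 0.750 as the square root of the median DESeq2 dispersion. The number of molecules was 74178 from bins above a TPM of 5, 246328 with 10 bins, 36341 with a robust spread, 37266 from squared differences and 56851 from genes in one library alone. The squared coefficient of variation levels off near 1.4 below about 10 TPM, which pulls the estimate from bins up. With 2 libraries that measure has an upper limit, so the fitted form could not hold for low genes. With the mean in place of the median, 0 lists stood outside their random range, against 1, though the erythroid difference was 0.36 as a mean and 0.32 as a median. Genes detected in both stayed within 1.5 times under all 9 settings, as did list members in total, while 26 of 120 counts for separate lists did not, 12 of them with detection in at least 1 library. Depth was not varied. The genes that differed 2-fold had a median of 2336 summed counts.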

Other observations

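The test of gene length was written before its result was seen, after the pattern it bears on had been found.

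Several ventral and neuronal genes not taken by the naming rule, and picked here after their values were seen, were split between the libraries. Such splits were common among all genes of like level. The share with under 1% of counts in one library was 53.6% from 5 to 10 TPM, 43.3% from 10 to 20 and 16.4% from 20 to 50. These picks therefore do not show a regional difference between the pools. Lhx6 and Lhx8, which act in the medial ganglionic eminence, were at 33.4 and 17.8 TPM in replicate 1 and at 0 in replicate 2. Dlx5 was at 1.02 TPM in replicate 1 and at 59.6 in replicate 2. Reln and Calb2, expressed by the earliest cortical neurons, were at 0.02 and 0 TPM in replicate 1 and at 25.0 and 21.6 in replicate 2, while Snap25 was at 69.3 and 0.59. Among erythroid genes, Slc4a1 was at 0.17 and 30.1 TPM and Klf1 at 13.9 ± 18.5 (SD, n = 2), nearly all of it in replicate 1. Of 8 haemoglobin genes, 7 were higher in replicate 2, or 6 after the shift of all genes was removed. That shift is larger than the one of abundant genes.

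Few spike-ins were read at low levels, while many genes were. The 7 ERCC rows read in one library alone had a median of 30.1 TPM there (22.4 to 120), and no ERCC row had a mean TPM from 1 to 10, while 3427 genes did. Another ERCC row had 0.08 TPM in both libraries, and a row with a higher mean had 3.97 in replicate 1. The 3309 genes read in one library alone, which may hold under 1% of their counts in the other, had a median of 16.3 TPM. A candidate explanation is that long transcripts give fewer reads per base for each molecule, which was tested by the Spearman rho of TPM with gene length over those genes. It was -0.26, short of the -0.3 set beforehand as needed and beyond the -0.1 that would have spoken against it, so the test left the explanation open. By length, the median was 21.1 TPM below 1000 bases, 22.0 from 1000 to 2000, 15.2 from 2000 to 4000 and 9.38 above 4000.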
